A study of Mus musculus with 33 samples.

How the data were processed

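Gene expression was measured by sequencing polyadenylated RNA from 11 mouse bone marrow populations, with 3 libraries each. Per the labels, stem and progenitor cells were depleted of lineage-positive cells with an antibody cocktail and magnetic beads before staining and sorting, mature cells were stained and sorted, and RNA was extracted with TRIzol. The table holds raw read counts per gene as deposited by the authors, whose processing notes name cutadapt, HISAT2, HTSeq and DESeq2 and the build mm39. Versions, annotation release, strandedness and sort gates were not given in the sources used here. Each of the 33 columns matched 1 library by its name, and no column was left out. Library totals ran from 11997186 (BM 1) to 32022325 counts (MEP 1). Of 56748 gene IDs 12153 had no count in any library, and 52073 matched a symbol in GENCODE M21, an annotation of GRCm38, from which GC content and transcript length were also taken. No coordinates were used. IDs without a symbol held at most 0.32% of the counts of a library, and 67 symbols were shared by several IDs. The ATP synthase genes were found under their older symbols (Atp5a1, Atp5b, Atp5c1).

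Counts were filtered by group (filterByExpr), which left 20464 genes, scaled by the trimmed mean of M-values (TMM, population mean factors from 0.591 in GMP to 1.64 in ST-HSC), and fitted with 1 mean per population by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with 22 residual degrees of freedom. The common biological coefficient of variation was 2.67%, so very small changes passed. Fold changes, standard errors and Benjamini-Hochberg adjusted p-values come from this fit, with 0.05 as the threshold, and counts per fold give genes changed by 2-fold or more in estimate. Levels are TMM-scaled counts (CPM), given as mean ± SD of 3 libraries. Where a group had no count, the fold is a bound against 3 counts over that group, and where it had 1 to 3 counts only the CPM values are given. The pooled comparison weighted each population equally, and the last comparison tested the difference of 2 log2 fold changes.

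The gene lists, the comparisons, the tests and most alternatives were fixed before the data were examined. The 29 lists were written from general knowledge of these cell types: stem cell identity, lymphoid priming, granulocyte-monocyte progenitor, megakaryocyte, erythroid, neutrophil maturation, monocyte and macrophage, mast cell, basophil and eosinophil, B lineage, plasma cell, T lineage, NK cell, MHC class II presentation, plasmacytoid dendritic cell, stromal and endothelial, DNA replication, mitosis, ribosome biogenesis, oxidative phosphorylation, immediate-early and stress, DNA methylation, Polycomb repressive complexes 1 and 2, MLL/COMPASS, heterochromatin, histone acetylation and deacetylation, histone demethylases, chromatin remodelling, and cohesin and CTCF. Lists planned for a comparison were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of the comparison, and again with an estimated correlation. The test is competitive, against all other genes. Other lists are given as medians without a test.

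The genes named come from the 5 largest rises and falls (3 each way in the last 2 comparisons) with adjusted p below 0.05, at least 10 CPM on the higher side and no overlap between replicates (not asked of the last comparison), leaving out numbered predicted genes, mitochondrial and ribosomal protein genes, receptor segments and bare IDs. Genes named only by a clone number passed the rule in places and are not printed. Up to 4 members of each passing list were added, as were 13 genes of the sort gates, and 16 chromatin genes for the comparison of mature with stem cells. Markers of other cell types named beside them were chosen after their values were seen. Values of 2 of the genes fixed this way are not reported here.

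Alternatives were relative log expression factors, library size alone, no filter, DESeq2 1.42.0, limma-voom with quality weights, fits of the populations compared only, the replicate number as a block, and leaving out each library. Added later were a test against a 2-fold change, a fit without CLP, a per-library trend on GC content and length (known for 96.5% of the genes) taken out, and dispersion estimated before the fit, the fit used having been chosen for speed after the data were seen. In a simulated comparison 50 genes changed at each fold, too few to test the scaling. There edgeR called 82%, 96% and 98% of genes changed 1.5-fold, 2-fold and 4-fold with the right sign, and 0.05% of 19969 unchanged genes. The trend correction brought a planted Spearman rho of 0.94 between fold and GC content to 0.071, and length was not tested.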

Results

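Polyadenylated RNA from 11 mouse bone marrow populations was sequenced in 33 libraries, 3 per population. The series asks how epigenetic regulation takes part in the fate decisions of hematopoietic stem cells. The sorts were long-term and short-term hematopoietic stem cells (LT-HSC and ST-HSC), and multipotent (MPP), common myeloid (CMP), granulocyte-macrophage (GMP), megakaryocyte-erythroid (MEP) and common lymphoid (CLP) progenitors. The mature fractions were named by CD11b, B220 and CD3e (CD11b+ cells, B220+ cells and CD3e T cells), and the labels name no sort for the remaining population, whole bone marrow (BM). The number of genes at 1 CPM or more ranged from 10624 ± 54.5 (SD, n = 3) in MEP to 14947 ± 45 in LT-HSC. The 10 most abundant genes took 30.0% of the counts in BM, 21.8% in CD11b+ cells and 5.08% in CLP, and mitochondrial genes from 0.461% in CD11b+ cells to 5.41% in CMP. Libraries of 1 population were close, with a chi-square per gene of 1.03 to 1.38 for most pairs over genes with 20 to 2000 counts. The pairs with MEP replicate 1 gave 2.31 and 2.33 and those with CLP replicate 2 gave 1.89 and 2.0, against 21 for ST-HSC and LT-HSC and 192 for MEP and CMP. Over all genes the pairs gave 1.15 to 3.73, more than counting noise. The labels do not say that replicates came from separate animals, so all p-values here measure only the spread between these libraries, which may be technical.

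The genes behind the usual sort gates separated most populations. Kit, the stem cell factor receptor, stood at 547 ± 2.4 CPM (SD, n = 3) in LT-HSC, 478 ± 4.3 in ST-HSC and 339 ± 5.9 in MPP, and at 6.05 ± 0.20 in B220+ cells. Ly6a, which encodes Sca-1, was at 135 ± 2.8 in LT-HSC, 149 ± 1.2 in ST-HSC and 216 ± 4.9 in MPP, and at 15.2 ± 0.37 in CMP, 32.9 ± 1.5 in GMP, 1.08 ± 0.22 in MEP and 2.20 ± 0.23 in CLP. Slamf1, the CD150 gene, was at 35.5 ± 0.6 in LT-HSC and 0.333 ± 0.071 in ST-HSC, while Cd48 was at 4.95 ± 0.45 and 25.9 ± 1.4. Cd34 ran from 211 ± 5.4 in LT-HSC to 1790 ± 43 in GMP and was at 3.02 ± 1.5 in MEP. Fcgr3, the low-affinity IgG receptor of the myeloid gates, was at 369 ± 7.7 in GMP, 5.0 ± 0.27 in CMP and 1.69 ± 0.76 in MEP. Gata1, the erythroid transcription factor, was at 835 ± 13 in MEP and between 21 ± 1.2 and 80.6 ± 3.2 in the other stem and progenitor sorts. Il7r, the interleukin-7 receptor of lymphoid progenitors, was at 45.7 ± 2.8 in CLP and 42.9 ± 1.1 in CMP. The receptor gene Flt3 (253 ± 4.1 against 743 ± 1.2) and Dntt, terminal transferase (222 ± 5.3 against 2460 ± 15), were lower in CLP than in CMP, Rag1 was higher (log2 fold change 1.32, or 0.569 with the trend on GC content and length taken out), and the median over 16 lymphoid priming genes was 0.103 (CLP minus CMP). Against BM, Cd3e was 39.5-fold higher in CD3e T cells (202 ± 3.5 against 5.0 ± 0.67 CPM, edgeR adjusted p = 8.9e-103), and Itgam, which encodes CD11b, was 1.91-fold higher in CD11b+ cells (428 ± 27 against 225 ± 3.0, adjusted p = 5.6e-22). Ptprc, whose isoform carries B220, was lower in B220+ cells than in BM (862 ± 5.0 against 980 ± 2.2, log2 fold change -0.185, adjusted p = 5.5e-13), and the sign turned with scaling by library size alone (0.461).

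**Figure D1:**
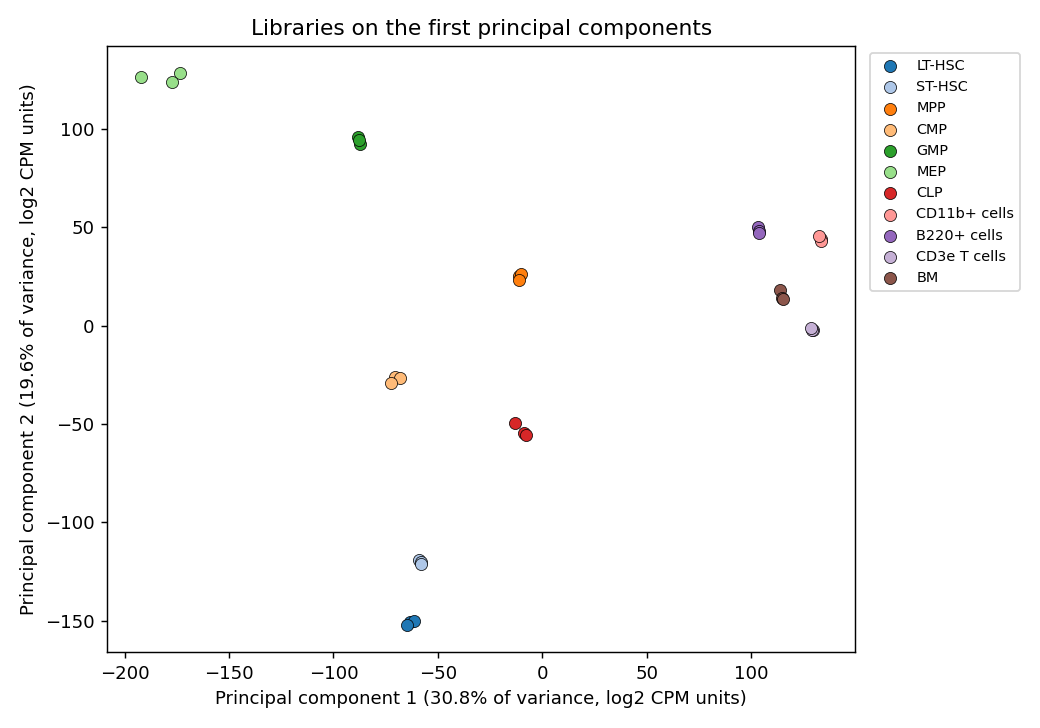
The 33 libraries on principal component 1 (30.8% of the variance) and principal component 2 (19.6%) of log2 CPM, 1 point per library, colored by population. The 3 libraries of each population lie together, LT-HSC beside ST-HSC, and the 3 mature fractions and BM at the high end of component 1.

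In the correlation of mean log2 CPM across genes, LT-HSC and ST-HSC were each other's nearest population (r = 0.963). GMP was nearest to MPP (0.945), CMP (0.933) and MEP (0.909), and CMP to CLP (0.882). Several sorts held abundant transcripts of other cell types, chosen for mention after their values were seen. MPP held 26900 ± 320 CPM of Ighm and 7380 ± 110 of Jchain, the antibody heavy and joining chains, and CD3e T cells held 13300 ± 85 of Igha. Prss34, a basophil protease, was at 3500 ± 59 in MPP, 3300 ± 100 in CLP and 4520 ± 5.6 in CD3e T cells. Col1a1, a collagen gene of stromal cells, was at 1470 ± 9.0 in LT-HSC and 858 ± 18 in CLP. S100a8, a calcium-binding protein gene of neutrophils, was at 2970 ± 170 in B220+ cells and 3950 ± 36 in CD3e T cells.

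**Figure D2:**
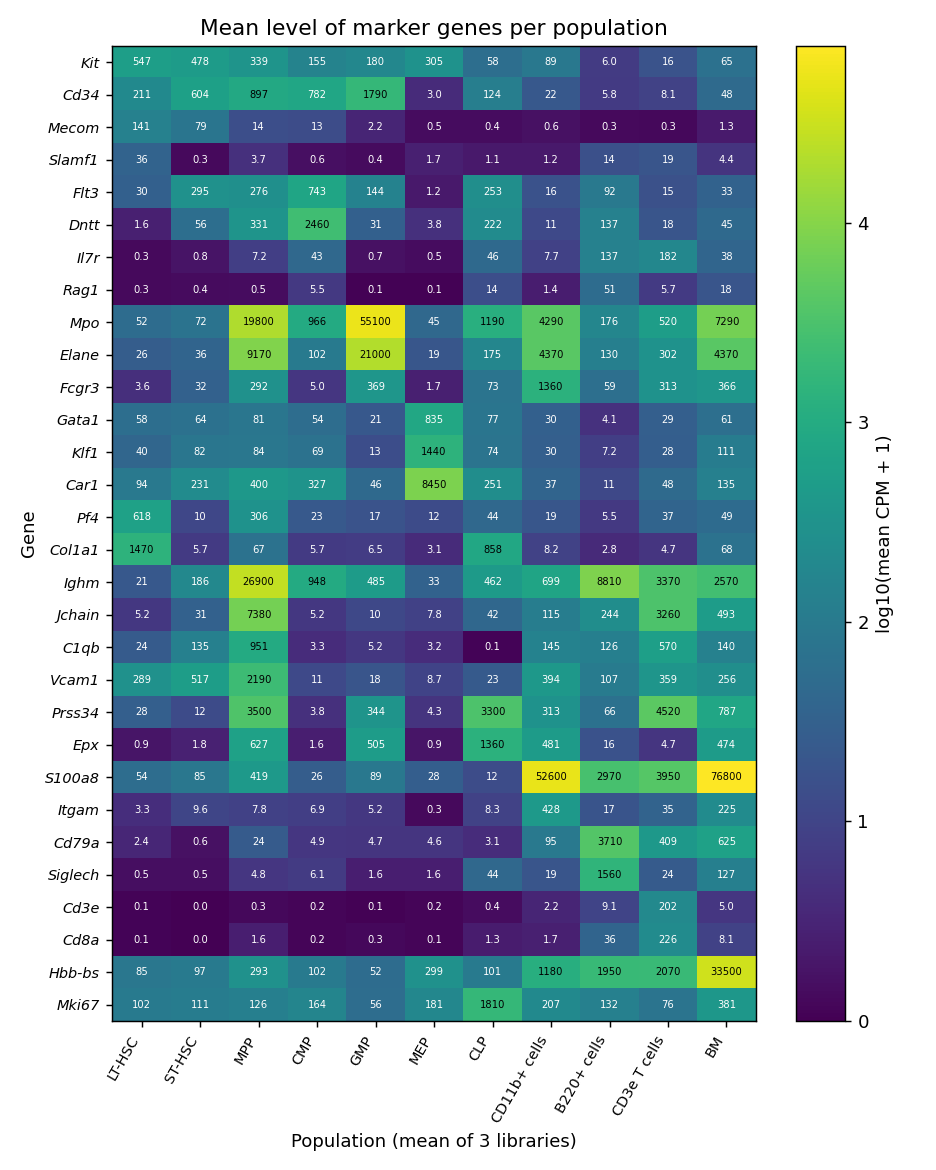
Mean expression of 30 marker genes in the 11 populations (n = 3 libraries each), as log10(CPM + 1). Gata1 and Klf1 peak in MEP, Mpo and Elane in GMP, and Dntt and Flt3 in CMP.

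The step from LT-HSC to ST-HSC, the first within the stem cell compartment, was marked by losses of megakaryocyte and stem cell genes and gains of lymphoid and myeloid progenitor genes, the myeloid gain not holding with an estimated correlation between genes. Slamf1 was 105-fold lower in ST-HSC (log2 fold change -6.71, SE 0.11, n = 3 against 3, adjusted p = 4.9e-86). Pf4, the platelet chemokine, was 60.9-fold lower (10.2 ± 0.83 against 618 ± 9.3 CPM), and Vwf, the von Willebrand factor gene, was 20.4-fold lower (5.92 ± 0.96 against 118 ± 3.2). Flt3 was 9.78-fold higher (295 ± 3.0 against 30.1 ± 0.59 CPM, adjusted p = 6.9e-107). Dntt was 32.8-fold higher (56.5 ± 0.98 against 1.64 ± 0.50).

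All 15 megakaryocyte genes were lower in ST-HSC (median log2 fold change -2.97, camera adjusted p = 3.47e-25, adjusted p = 0.00155 with an estimated correlation between genes, called p-est below), among them Itga2b at 15.4-fold and Treml1 at 40.2-fold. Of 26 stem cell identity genes, 22 were lower and 4 higher (median -0.92, adjusted p = 4.68e-14, p-est = 0.00155). Among 16 lymphoid priming genes, 14 were higher and 2 did not pass (median 1.28, adjusted p = 1.1e-11, p-est = 0.0121), including Satb1 at 5.26-fold, Tcf3 at 2.82-fold and Ikzf1 at 2.25-fold. The granulocyte-monocyte progenitor list had 14 of 18 genes higher, 2 lower and 2 not passing (median 0.68, adjusted p = 5.06e-06, p-est = 0.379). Monocyte and macrophage genes, not tested here, were higher by 2-fold or more in 11 of 18 and lower in 1 (median 1.70). The mitosis list had 15 of 20 genes lower, 1 higher and 4 not passing (median -0.19, adjusted p = 0.00303, p-est = 0.552).

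Ccl3, a chemokine, was 23.3-fold higher in ST-HSC (100 ± 3.9 against 4.30 ± 0.33 CPM) and Tlr7, a sensor of single-stranded RNA, 18.9-fold. The osteocalcin gene Bglap2 had no count in ST-HSC and 20.4 ± 0.39 CPM in LT-HSC, at least 675-fold lower against a floor of 3 counts over the group. It can share reads with its near copies, so its separate value is uncertain. Col2a1, the cartilage collagen, was 343-fold and Slc6a4, the serotonin transporter, 314-fold lower in ST-HSC. Likewise, 8 of 12 stromal and endothelial genes were lower by 2-fold or more (median -1.85, not tested), with Col1a1 at 5.71 ± 0.36 against 1470 ± 9.0 CPM. None of the 9 chromatin lists passed, with adjusted p from 0.113 (Polycomb repressive complex 1, heterochromatin, histone demethylases and chromatin remodelling) to 0.98 (DNA methylation, cohesin and CTCF). DNA replication, ribosome biogenesis, oxidative phosphorylation and immediate-early genes did not pass either. Without the GC and length trend, 5 chromatin lists passed as higher in ST-HSC, Polycomb repressive complex 1 (0.0403), MLL/COMPASS (0.0342), heterochromatin (0.0415), demethylases (0.0349) and remodelling (0.00702), as did ribosome biogenesis (0.0233) and immediate-early genes (0.0141). Median and mean differed in sign for replication (-0.05 and 0.01), histone acetylation (-0.04 and 0.03) and DNA methylation (0.00245 and -0.0225), and for cohesin (0.01 and -0.01) with a test that pointed up. In all, 6103 genes were higher and 6975 lower by edgeR, 1838 and 2377 of them by 2-fold or more. Adjusted over the list alone, the counts were those over all genes except for 4 in place of 3 lower oxidative phosphorylation genes, 7 in place of 6 Polycomb repressive complex 2 genes and 3 in place of 2 heterochromatin genes.

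Between ST-HSC and MPP, at the exit from the stem cell compartment, granulocyte-monocyte, cell cycle and respiratory genes rose and stem cell genes fell. Ms4a3, a gene of granulocyte-monocyte progenitors, was 143-fold higher in MPP (603 ± 13 against 4.19 ± 0.15 CPM, n = 3 each, log2 fold change 7.16, SE 0.045, adjusted p = 2.9e-130). Hlf, a stem cell transcription factor, was 9.51-fold lower (26.8 ± 1.8 against 256 ± 2.8 CPM, adjusted p = 9.0e-98). The largest rises included the eosinophil granule genes Prg2 at 3610 ± 76 against 7.88 ± 0.79 CPM (456-fold), Epx, eosinophil peroxidase (354-fold), and Prg3 (659-fold).

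Of 18 granulocyte-monocyte progenitor genes 17 were higher and 1 did not pass (median 3.49, camera adjusted p = 1.15e-15, p-est = 0.0383). Every one of the 20 mitosis genes (median 1.43) and of the 21 measured oxidative phosphorylation genes (median 1.20) was higher, each list with adjusted p = 1.15e-15, p-est = 0.0383. All 20 replication genes were higher too (median 0.92, adjusted p = 5.95e-11, p-est = 0.0415), though their median was -0.0688 with library size alone. The ATP synthase gene Atp5b was 4.24-fold higher. Stem cell identity had 22 of 26 genes lower and 4 higher (median -1.80, adjusted p = 5.64e-09, p-est = 0.00568). The megakaryocyte list went up, with 12 of 15 genes higher, 2 lower and 1 not passing (median 1.17, adjusted p = 0.000659, p-est = 0.0769), and Pf4 30.2-fold higher. Ribosome biogenesis had 16 of 18 genes higher, 1 lower and 1 not passing (median 0.66, adjusted p = 1.58e-07, p-est = 0.0921). Npm1, nucleophosmin, was 2.38-fold higher, while Ncl, Dkc1 and the median of this list turned to -0.0491, -0.22 and -0.329 with scaling by library size alone. Lymphoid priming was split, with 9 of 16 genes higher, 6 lower and 1 not passing (median 0.92, adjusted p = 0.0215, p-est = 0.301). Ikzf1, 1.63-fold higher, and the list median turned to -0.286 and -0.0712 with library size alone.

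Among the chromatin lists, histone demethylases had 11 of 16 measured genes lower, 2 higher and 3 not passing (median -0.48, adjusted p = 0.00135, p-est = 0.0769), with Kdm6b 4.05-fold and Jmjd1c 3.15-fold lower. Polycomb repressive complex 1 had 13 of 20 lower, 3 higher and 4 not passing (median -0.22, adjusted p = 0.0495, p-est = 0.386), with Phc3 4.12-fold, Cbx7 2.10-fold and Bmi1 1.72-fold lower. Its adjusted p was 0.0548 without ST-HSC replicate 2, 0.0528 without ST-HSC replicate 3 and 0.0583 without MPP replicate 1, and neither list passed with the trend with GC content and length taken out (called without the GC and length trend below; 0.334 for demethylases, 0.479 for Polycomb repressive complex 1). DNA methylation (median -0.24, mean 0.13), cohesin and CTCF (0.00 and -0.14) and the other 5 chromatin lists did not pass. Transcripts of mature cells moved with these groups: 12 of 12 mast cell, basophil and eosinophil genes (median 6.94) and 7 of 9 plasma cell genes (median 3.94) were higher by 2-fold or more, and 8 of 12 stromal and endothelial genes were lower (median -2.46), none of these lists being tested here. The largest falls were Kcnj8 (74.1-fold), Cyp4b1 (74.0-fold) and Gpihbp1, the lipoprotein lipase anchor of capillaries (71.0-fold). In all, 6879 genes were higher and 8178 lower, 3013 and 4383 by 2-fold or more. Scaling by library size alone moved the median of all genes by -0.983 and the split to 2271 higher and 15159 lower, and relative log expression factors moved it by -0.101. Counts adjusted over the list alone were those over all genes except for 12 in place of 11 higher histone acetylation and 14 in place of 13 higher remodelling genes.

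CMP were then compared with MPP, the myeloid branch of the hierarchy in the design. Granulocyte-monocyte, basophil and megakaryocyte genes were lower in CMP, and lymphoid genes such as Flt3 and Notch1 were higher. No list call held with an estimated correlation, here or in the 9 comparisons that follow. Fcgr3 was 58.5-fold lower (5.0 ± 0.27 against 292 ± 3.1 CPM, n = 3 each, log2 fold change -5.87, SE 0.049, adjusted p = 1.2e-116) and Ms4a3 52.4-fold lower. Gata2, a stem and progenitor transcription factor, was 8.28-fold lower (30.4 ± 1.0 against 253 ± 1.6 CPM). Flt3 was 2.70-fold higher (743 ± 1.2 against 276 ± 1.6, adjusted p = 1.2e-80) and Notch1, the receptor of T lineage specification, 4.94-fold higher (143 ± 7.7 against 29.1 ± 0.36). Dntt stood at 2460 ± 15 and 331 ± 7.3 CPM.

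The granulocyte-monocyte progenitor list had 15 of 18 genes lower, 2 higher and 1 not passing (median -3.35, camera adjusted p = 7.49e-11, p-est = 0.0785). Mast cell, basophil and eosinophil genes were lower in 11 of 12 with 1 not passing (median -7.61, adjusted p = 3.1e-11, p-est = 0.0785). Mcpt8, a basophil protease, was 162-fold, Epx 402-fold, Prss34 957-fold and Prg2 532-fold lower, and Jchain was 1540-fold lower. Megakaryocyte genes were lower in 12 of 15, with 2 higher and 1 not passing (median -1.72, adjusted p = 1.97e-05, p-est = 0.0785), Pf4 by 13.6-fold. Not tested here, monocyte and macrophage genes (15 of 18, median -5.68), neutrophil maturation genes (15 of 18, median -1.40) and plasma cell genes (7 of 9, median -2.78) were lower by 2-fold or more. Stem cell identity had 17 of 26 lower, 5 higher and 4 not passing (median -0.91, adjusted p = 0.000566, p-est = 0.112), with Ly6a 14.3-fold lower and Tek, the angiopoietin receptor, 65.2-fold lower. Lymphoid priming had 9 of 16 higher, 6 lower and 1 not passing (median 0.71, adjusted p = 0.00601, p-est = 0.229), with Satb1 4.81-fold higher and Tcf3 2.75-fold lower. Erythroid genes were lower in 14 of 22, higher in 7, with 1 not passing, and adjusted over the list alone 15 were lower (median -0.47, adjusted p = 0.0427, p-est = 0.356). That call was lost with library size alone (median 0.218, adjusted p = 0.366), without the GC and length trend (0.421), with relative log expression factors (0.0612) and without the CLP libraries (0.0507). In it Tfrc, the transferrin receptor, was 1.64-fold higher and Hbb-bs 2.86-fold lower by edgeR, with adjusted p = 0.21 by limma-voom.

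Oxidative phosphorylation genes were lower in 18 of 21 with 3 not passing (median -0.69, adjusted p = 1.29e-09, p-est = 0.107), Atp5b by 2.62-fold. Replication (13 of 20 lower, 5 higher, 2 not passing, median -0.32, adjusted p = 0.00668, p-est = 0.356) and mitosis (15 lower, 4 higher, 1 not passing, median -0.28, adjusted p = 0.00109, p-est = 0.302) were lower by TMM scaling, while their medians were 0.36 and 0.401 with library size alone. Mcm6 was 2.01-fold lower, and Mcm5, 1.59-fold lower, turned to 0.0106 with library size alone. Immediate-early and stress genes were higher in 12 of 16 and lower in 4 (median 0.23, adjusted p = 0.00178, p-est = 0.241), with Fosb at 4.84-fold and Egr1 at 2.74-fold. The largest rises were Cxcl2, a neutrophil chemokine, at 18.9-fold (290 ± 6.9 against 15.4 ± 0.30 CPM), Nr4a3 at 16.5-fold and Tnfsf11, the RANK ligand gene, at 15.6-fold.

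Among chromatin genes, histone demethylases were higher in 14 of 16, lower in 1, with 1 not passing (median 0.49, adjusted p = 4.76e-05, p-est = 0.0785), Kdm6b by 7.92-fold and Jmjd1c by 3.70-fold. All 10 cohesin and CTCF genes were higher (median 0.49, adjusted p = 8.73e-05, p-est = 0.0785), Ctcf by 1.72-fold. Chromatin remodelling had 21 of 36 higher, 8 lower and 7 not passing (median 0.28, adjusted p = 0.0141, p-est = 0.302). The cohesin and remodelling calls were lost without the GC and length trend (0.083 and 0.499). Ribosome biogenesis (adjusted p = 0.132) and the other 6 chromatin lists did not pass. In all, 7156 genes were higher and 7166 lower, 3261 and 3161 by 2-fold or more. Library size alone moved the median of all genes by 0.675 and the split to 13061 higher and 3099 lower. Other counts adjusted over the list alone were those over all genes.

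For the lymphoid branch, CLP were compared with MPP. Chromatin-regulator genes were higher in CLP, and stem cell, granulocyte-monocyte, respiratory and immediate-early genes were lower, though 2 of the 9 chromatin lists did not pass and no list did with an estimated correlation. Rad21, a cohesin subunit, was 13.8-fold higher (412 ± 5.3 against 29.9 ± 2.8 CPM, n = 3 each, log2 fold change 3.78, SE 0.038, adjusted p = 1.1e-108), Ctcf, the insulator protein gene, 8.83-fold and Chd4, the NuRD remodeller, 6.66-fold (544 ± 10 against 81.5 ± 3.0). Ly6a was 96.8-fold lower (2.20 ± 0.23 against 216 ± 4.9 CPM, adjusted p = 9.1e-113), and Atp5b was 5.72-fold lower. Log2 fold changes in this comparison rose with transcript length (Spearman rho 0.502 across genes, which are not independent replicates), a trend present in the values below.

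All 10 cohesin and CTCF genes were higher (median 1.95, camera adjusted p = 4.9e-07, p-est = 0.103). Chromatin remodelling had 30 of 36 higher, 4 lower and 2 not passing (median 1.55, adjusted p = 9.4e-09, p-est = 0.103), with Baz1a and Chd3 each 10.2-fold and Arid1a 5.27-fold higher. MLL/COMPASS had 12 of 16 higher and 4 lower (median 1.63, adjusted p = 0.000783, p-est = 0.221), with the histone H3 lysine methyltransferase genes Kmt2b 30.7-fold, Kmt2d 12.1-fold and Kmt2a 7.73-fold higher. Heterochromatin genes were higher in 10 of 12 with 2 not passing (median 1.19), and histone demethylases in 12 of 16 with 4 lower (median 1.34), both with adjusted p = 0.000539, p-est = 0.145. Polycomb repressive complex 1 had 15 of 20 higher, 4 lower and 1 not passing (median 1.05, adjusted p = 0.00321, p-est = 0.248). DNA methylation had 9 of 14 higher, 3 lower and 2 not passing (median 0.74, adjusted p = 0.0307, p-est = 0.248), with the methyl-CpG binding gene Mbd2 19.2-fold and the dioxygenase genes Tet2 6.50-fold and Tet3 5.22-fold higher. Its median turned to -0.0684 without the GC and length trend, when Polycomb repressive complex 1 (0.193), heterochromatin (0.0904) and demethylases (0.549) no longer passed. Polycomb repressive complex 2 (8 of 12 higher, 3 lower, adjusted p = 0.0562) and histone acetylation (16 of 29 higher, 11 lower, adjusted p = 0.116) did not pass.

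Oxidative phosphorylation genes were all lower, 21 of 21 (median -1.58, adjusted p = 4.9e-13, p-est = 0.103). Immediate-early genes were lower in 13 of 16 and higher in 3 (median -1.81, adjusted p = 0.000107, p-est = 0.145), Nr4a1 by 14.6-fold. Ribosome biogenesis had 13 of 18 lower, 4 higher and 1 not passing (median -0.89, adjusted p = 0.00341, p-est = 0.297), and replication 11 of 20 lower, 7 higher and 2 not passing (median -0.23, adjusted p = 0.0407, p-est = 0.491), a call lost with library size alone (median 0.357, adjusted p = 0.863). Mcm6 was 2.88-fold lower, while the proliferation antigen gene Mki67 was at 1810 ± 25 CPM in CLP and 126 ± 4.8 in MPP, and mitosis did not pass (10 of 20 higher, 9 lower, adjusted p = 0.344). Stem cell identity had 17 of 26 lower, 6 higher and 3 not passing (median -1.75, adjusted p = 0.00439, p-est = 0.221), and granulocyte-monocyte progenitor genes 14 of 18 lower and 4 higher (median -1.50, adjusted p = 0.000178, p-est = 0.248), with Cebpa, a myeloid transcription factor, 9.28-fold higher. The B lineage list did not pass, with 7 of 20 genes higher, 12 lower and 1 not passing (median -0.86, adjusted p = 0.289), nor did lymphoid priming (8 of 16 higher, 6 lower, adjusted p = 0.344), T lineage (7 of 22 higher, 8 lower, adjusted p = 0.917) or NK cell genes (3 of 12 higher, 4 lower, adjusted p = 0.829, with a median of 0.08 and a test pointing down). Plasmacytoid dendritic cell genes were higher in 8 of 10 and lower in 2 (median 2.55, adjusted p = 0.0198, p-est = 0.248), Runx2 by 11.8-fold, and Tcf4, 2.41-fold higher, turned to -0.0715 without the GC and length trend.

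The largest falls in CLP included macrophage genes, with the secreted macrophage protein gene Cd5l 2040-fold and Fcna, ficolin A, 2760-fold lower, C1qb at 0.120 ± 0.022 against 951 ± 8.1 CPM and C1qa at 0.168 ± 0.12 against 572 ± 11. The rises were led by Pdzd4 at 248-fold, Sav1, a Hippo pathway scaffold, at 165-fold and Prr33 at 113-fold. Stromal and endothelial genes were higher by 2-fold or more in 10 of 12 and lower in 1 (median 3.10, not tested), with Col1a1 at 858 ± 18 against 67.0 ± 3.4 CPM, and Epx was at 1360 ± 51 against 627 ± 9.5. In all, 8098 genes were higher and 7650 lower, 5759 and 4586 by 2-fold or more. Library size alone moved the median of all genes by 0.566 and the split to 10843 higher and 4970 lower, and the fit without the GC and length trend moved it by 0.172. No count differed adjusted over the list alone.

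**Figure D3:**
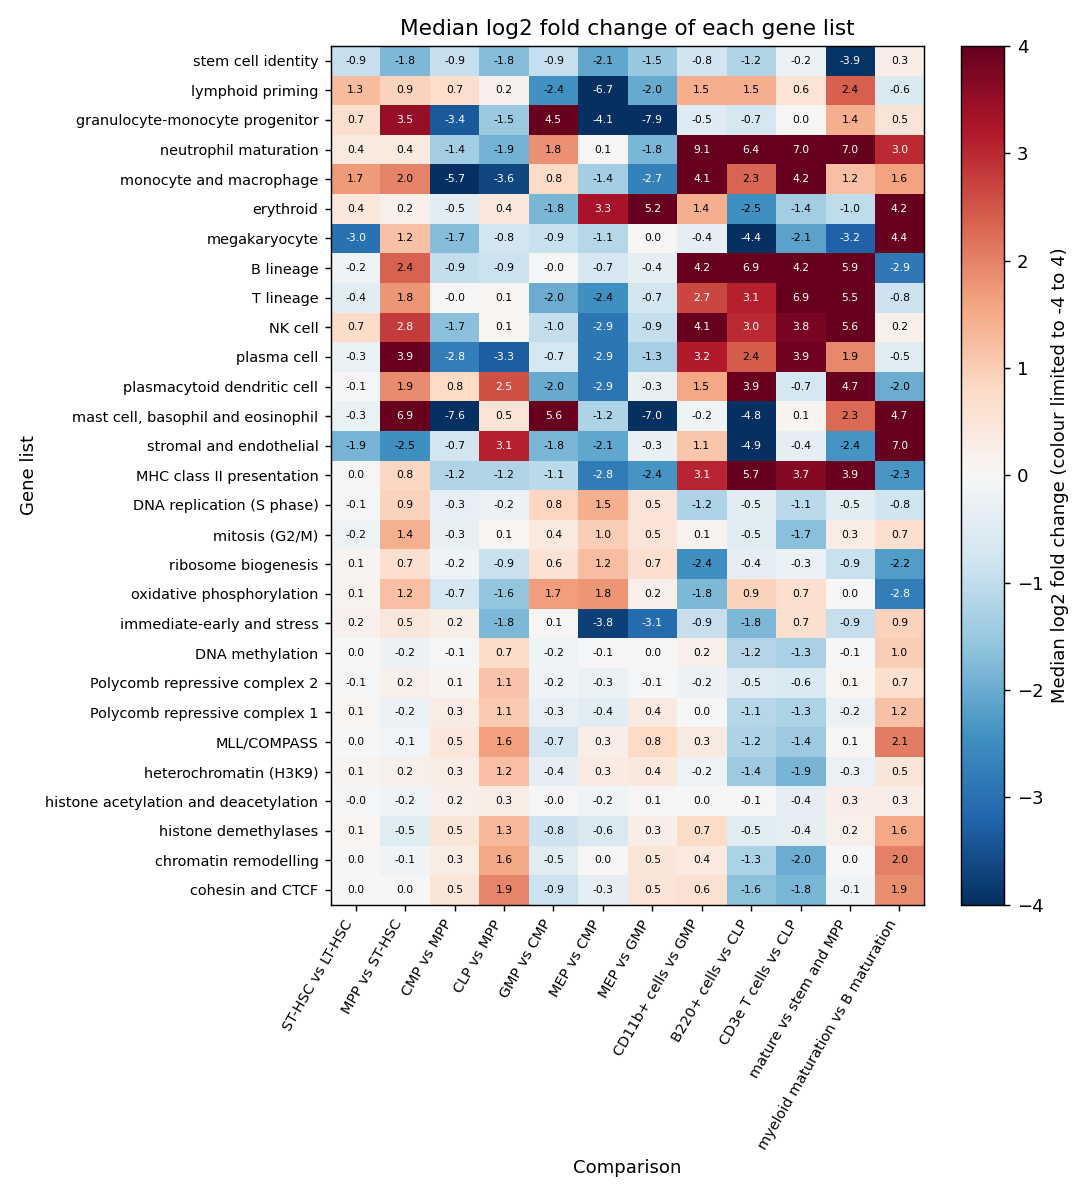
Median log2 fold change of each of the 29 gene lists (vertical axis) in each of the 12 comparisons (horizontal axis), with colors limited to the range from -4 to 4. Chromatin lists are higher in CLP than in MPP and lower in B220+ cells and CD3e T cells than in CLP, but the DNA methylation median in CLP against MPP turned to -0.0684 without the GC and length trend; with library size alone, medians of cell cycle, ribosome biogenesis and other lists turn sign in the comparisons of MPP with ST-HSC, CMP and CLP with MPP, GMP with CMP, and mature with stem cells.

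GMP against CMP, the granulocyte-macrophage branch, gave higher granulocyte-monocyte progenitor, respiratory and replication genes and lower erythroid genes in GMP. Lymphoid priming, not tested here, had 11 of 16 genes lower and 2 higher by 2-fold or more, and mast cell, basophil and eosinophil genes 11 of 12 higher (median 5.58). Elane, neutrophil elastase, was 208-fold higher (21000 ± 610 against 102 ± 4.6 CPM, n = 3 each, log2 fold change 7.70, SE 0.085, adjusted p = 3.0e-29), Ms4a3 141-fold and Fcgr3 74.0-fold. Mpo, myeloperoxidase, was at 55100 ± 760 CPM in GMP and 966 ± 5.1 in CMP. Dntt was 79.8-fold lower (30.9 ± 0.41 against 2460 ± 15, adjusted p = 5.0e-30) and Il7r 65.6-fold lower (0.668 ± 0.094 against 42.9 ± 1.1).

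All 18 granulocyte-monocyte progenitor genes were higher (median 4.52, camera adjusted p = 4.43e-15, p-est = 0.0629). Monocyte and macrophage genes were higher in 13 of 18, lower in 1, with 4 not passing (median 0.80, adjusted p = 0.000614, p-est = 0.334; median -0.373 with library size alone), F13a1, a coagulation factor subunit, by 21.4-fold and the chemokine receptor Ccr2 by 8.01-fold. Neutrophil maturation genes were higher in 16 of 18 and lower in 2 (median 1.82, adjusted p = 0.00197, p-est = 0.468), at low levels such as 6.64 ± 0.32 CPM of Ly6g. Eosinophil genes were among the largest rises, Prg2 by 379-fold and Epx by 325-fold. Erythroid genes were lower in 20 of 22 and higher in 2 (median -1.82, adjusted p = 5.66e-09, p-est = 0.0629), with Rhag, a red cell membrane protein, 12.7-fold lower. Stem cell identity had 16 of 26 lower, 4 higher and 6 not passing (median -0.92, adjusted p = 0.029, p-est = 0.309), a call lost with library size alone (0.163) and without the GC and length trend (0.152). Mllt3 was 4.68-fold and Hoxa9 2.45-fold lower, and Gata2 2.43-fold higher. Sema3d was 77.4-fold and Arpp21 78.3-fold lower, and megakaryocyte genes did not pass (adjusted p = 0.429).

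Oxidative phosphorylation genes were higher in 20 of 21 with 1 not passing (median 1.66, adjusted p = 1.55e-16, p-est = 0.0629), Atp5b by 5.29-fold (9400 ± 290 against 1780 ± 39 CPM), while the mitochondrial share of counts was lower in GMP (1.20% against 5.41%). Replication had 17 of 20 higher, 2 lower and 1 not passing (median 0.85, adjusted p = 5.26e-07, p-est = 0.136), with Mcm5 3.85-fold higher, a call lost with library size alone (median -0.325, adjusted p = 0.286). Mitosis (12 of 20 higher, 8 lower, median 0.40, adjusted p = 0.0369, p-est = 0.529) and ribosome biogenesis (16 of 18 higher, 2 lower, median 0.58, adjusted p = 7.48e-06, p-est = 0.187) turned to medians of -0.771 and -0.593 with library size alone. Ccnb1, Npm1 and Nop2, higher by 2.18-fold, 1.83-fold and 1.94-fold, turned to -0.0449, -0.301 and -0.218. Histone demethylases were lower in 14 of 16, higher in 1, with 1 not passing (median -0.84, adjusted p = 9.5e-05, p-est = 0.0629), Kdm6b by 11.9-fold and Jmjd1c by 7.48-fold. All 10 cohesin and CTCF genes were lower (median -0.87, adjusted p = 1.8e-05, p-est = 0.0629), Nipbl by 2.76-fold, and chromatin remodelling had 24 of 36 lower, 9 higher and 3 not passing (median -0.48, adjusted p = 0.0204, p-est = 0.334). Without the GC and length trend, the cohesin call was lost (0.207), Pds5a, 2.09-fold lower, no longer passed (0.61), and the remodelling median turned to 0.00724. Chd2 was 4.64-fold lower, and Mta2, 1.91-fold higher, turned to -0.239 with library size alone, where Smarcb1, 2.26-fold higher, no longer passed (0.79). The other 6 chromatin lists and the immediate-early list (median 0.06, mean -0.37) did not pass, and for histone acetylation the test pointed up with a median of -0.04. In all, 6510 genes were higher and 8565 lower, 3234 and 5715 by 2-fold or more. Library size alone moved the median of all genes by -1.15 and the split to 1991 higher and 15079 lower. Only 1 count differed adjusted over the list alone, with 8 in place of 7 immediate-early genes lower.

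MEP against CMP, the megakaryocyte-erythroid branch, gave higher erythroid and cell cycle genes and lower lymphoid and immediate-early genes in MEP. Klf1, the erythroid transcription factor, was 20.8-fold higher (1440 ± 56 against 69.3 ± 1.2 CPM, n = 3 each, log2 fold change 4.38, SE 0.030, adjusted p = 5.0e-124), and Gata1 15.5-fold. The carbonic anhydrase genes Car2 and Car1 were 27.3-fold and 25.8-fold higher, Car2 at 22200 ± 730 CPM, and the water channel gene Aqp1 28.6-fold. Flt3 was 705-fold lower (1.18 ± 0.62 against 743 ± 1.2, adjusted p = 1.7e-126), Dntt 730-fold and Notch1 302-fold lower.

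All 22 erythroid genes were higher (median 3.30, camera adjusted p = 3.14e-14, p-est = 0.0665), with Blvrb, biliverdin reductase B, 19.3-fold higher. Megakaryocyte genes did not pass, with 3 of 15 higher, 11 lower and 1 not passing (median -1.14, adjusted p = 0.0566). Lymphoid priming had 13 of 16 lower and 3 higher (median -6.66, adjusted p = 7.69e-05, p-est = 0.24), with Tcf3 8.61-fold higher. The granulocyte-monocyte progenitor list had 16 of 18 lower, 1 higher and 1 not passing (median -4.10, adjusted p = 2.3e-06, p-est = 0.24), with Spi1, the PU.1 gene, 54.6-fold and Ly86 106-fold lower. Stem cell identity had 17 of 26 lower, 6 higher and 3 not passing (median -2.08, adjusted p = 0.0236, p-est = 0.24), a call lost with library size alone (0.233). Mast cell, basophil and eosinophil genes did not pass (adjusted p = 0.0817).

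Replication (19 of 20 higher, 1 lower, median 1.46, adjusted p = 1.22e-10, p-est = 0.121) and mitosis (15 of 20 higher, 3 lower, 2 not passing, median 0.97, adjusted p = 1.95e-05, p-est = 0.24) were higher, Rrm2, a ribonucleotide reductase subunit, by 5.27-fold and Ccnb1, cyclin B1, by 4.15-fold. All 18 ribosome biogenesis genes (median 1.22, adjusted p = 2.33e-10) and all 21 oxidative phosphorylation genes (median 1.76, adjusted p = 5.85e-15) were higher, each with p-est = 0.121. Immediate-early genes were lower in 15 of 16 and higher in 1 (median -3.75, adjusted p = 2.33e-10, p-est = 0.13), Nr4a1 by 137-fold (11.1 ± 2.1 against 1480 ± 24 CPM), Egr1 by 29.0-fold and Fos by 11.1-fold. Of the chromatin lists only histone demethylases passed, with 11 of 16 lower, 3 higher and 2 not passing (median -0.62, adjusted p = 0.0193, p-est = 0.233), Kdm6b by 7.88-fold, and that call was lost without the GC and length trend (0.231). Chromatin remodelling had a median of 0.04 and a mean of -0.21. In all, 6973 genes were higher and 9058 lower, 3875 and 6983 by 2-fold or more. Library size alone moved the median of all genes by -0.918 and the split to 3405 higher and 13580 lower. No count differed adjusted over the list alone.

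MEP were also set directly against GMP, the sister branch. Mpo was 1360-fold lower in MEP (44.7 ± 22 against 55100 ± 760 CPM, n = 3 each, log2 fold change -10.4, SE 0.15, adjusted p = 1.5e-26), Ctsg, cathepsin G, 1410-fold and Elane 1240-fold. Car1 was 190-fold higher (8450 ± 170 against 45.8 ± 9.8, adjusted p = 8.9e-35), Klf1 113-fold and Gata1 40.1-fold.

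Erythroid genes were higher in 21 of 22 and lower in 1 (median 5.22), and all 18 granulocyte-monocyte progenitor genes were lower (median -7.87), each list with camera adjusted p = 5.65e-18. All 12 mast cell, basophil and eosinophil genes, not tested here, were lower by 2-fold or more (median -7.01). The p-est was 0.105 for the erythroid and 0.113 for the progenitor list. Neutrophil maturation had 17 of 18 lower and 1 not passing (median -1.82, adjusted p = 7.93e-05, p-est = 0.307), Padi4 by 37.4-fold. Immediate-early genes were lower in 15 of 16 and higher in 1 (median -3.08, adjusted p = 3.26e-13, p-est = 0.113), Fos by 16.9-fold and Jun by 11.1-fold. Replication (16 of 20 higher, 3 lower, 1 not passing, median 0.50, adjusted p = 7.93e-05), mitosis (17 higher, 2 lower, 1 not passing, median 0.51, adjusted p = 1.45e-05) and ribosome biogenesis (16 of 18 higher, 1 lower, 1 not passing, median 0.66, adjusted p = 4.47e-08) were higher. The p-est was 0.193 for replication and mitosis and 0.132 for ribosome biogenesis. Stem cell identity (16 of 26 lower, 6 higher, 4 not passing, median -1.51, adjusted p = 0.0454, p-est = 0.248) and oxidative phosphorylation (12 of 21 higher, 7 lower, 2 not passing, median 0.22, adjusted p = 0.0392, p-est = 0.576) both lost their call without MEP replicate 1, each at 0.063, and with relative log expression factors (0.0561 and 0.0838).

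MLL/COMPASS had 14 of 16 higher, 1 lower and 1 not passing (median 0.80, adjusted p = 0.000174, p-est = 0.193), with Kmt2c 2.57-fold higher. Heterochromatin had 9 of 12 higher, 1 lower and 2 not passing (median 0.43, adjusted p = 0.00873, p-est = 0.193), with Suv39h2, a histone H3 methyltransferase, 5.09-fold and Cbx5, the HP1 alpha gene, 2.90-fold higher. All 10 cohesin and CTCF genes were higher (median 0.50, adjusted p = 0.00152, p-est = 0.193), Wapl by 2.90-fold, a call lost without the GC and length trend (0.369), where Nipbl, 1.59-fold higher, no longer passed (0.055). Chromatin remodelling had 20 of 36 higher, 8 lower and 8 not passing (median 0.47, adjusted p = 0.0103, p-est = 0.248), with Phf10 11-fold higher and Arid1b 3.28-fold lower. Heterochromatin (0.0605) and remodelling (0.0646) did not pass with only MEP and GMP in the fit. Histone demethylases (adjusted p = 0.107), both Polycomb lists, DNA methylation (median 0.05, mean -0.16), histone acetylation (0.06 and -0.16) and megakaryocyte genes (7 of 15 higher, 6 lower, median 0.03, mean -0.15, adjusted p = 0.675) did not pass. In all, 6410 genes were higher and 6361 lower, 2899 and 4216 by 2-fold or more, and library size alone moved the median of all genes by 0.17. The counts that differed adjusted over the list alone were 2 in place of 1 lower heterochromatin and 5 in place of 4 lower demethylase genes.

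CD11b+ cells against GMP followed myeloid maturation, with neutrophil genes higher and growth and respiratory genes lower. Ly6g, the neutrophil surface antigen, was 126-fold higher in CD11b+ cells (839 ± 14 against 6.64 ± 0.32 CPM, n = 3 each, log2 fold change 6.97, SE 0.049, adjusted p = 7.7e-128), the chemokine receptor Cxcr2 115-fold and Il1b 496-fold. Cd34 was 82.9-fold lower (21.5 ± 1.3 against 1790 ± 43, adjusted p = 3.9e-40), Npm1 13.4-fold and Atp5b 8.21-fold lower. Gpr27 had no count in GMP (at least 286-fold higher against 3 counts over the group), and Ncs1 was 128-fold lower.

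All 18 neutrophil maturation genes were higher (median 9.10, camera adjusted p = 1.24e-12, p-est = 0.124). Monocyte and macrophage genes were higher in 15 of 18 and lower in 3 (median 4.13, adjusted p = 2.24e-05, p-est = 0.215), Adgre1, the F4/80 gene, by 17.9-fold. Of other lineages, the B lineage list had 19 of 20 higher and 1 lower (median 4.19, adjusted p = 3.41e-06, p-est = 0.177), at levels such as 32.6 ± 0.40 CPM of Bank1. The erythroid list had 18 of 22 higher, 2 lower and 2 not passing (median 1.45, adjusted p = 6.46e-05, p-est = 0.196), with Hbb-bs at 1180 ± 10 against 52.2 ± 1.6 CPM and Alas2, a heme synthesis gene, 45.1-fold higher. MHC class II presentation (6 of 10 higher, 3 lower, median 3.06, adjusted p = 0.0962), NK cell (10 of 12 higher, 2 lower, median 4.08, adjusted p = 0.0753) and granulocyte-monocyte progenitor genes (8 of 18 higher, 10 lower, adjusted p = 0.598) did not pass.

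Replication (18 of 20 lower, 1 higher, 1 not passing, median -1.24, adjusted p = 1.39e-08), ribosome biogenesis (17 of 18 lower, 1 not passing, median -2.44, adjusted p = 8.76e-12) and oxidative phosphorylation (21 of 21 lower, median -1.81, adjusted p = 1.66e-14) fell, each with p-est = 0.124. Mitosis did not pass (11 of 20 higher, 9 lower, adjusted p = 0.757). Among chromatin lists, histone demethylases passed with 13 of 16 higher and 3 lower (median 0.72, adjusted p = 0.00545, p-est = 0.124), Kdm7a by 27.2-fold, a call lost without the GC and length trend (0.304). DNA methylation had a median of 0.20 and a test pointing down, Polycomb repressive complex 1 had a median of 0.01 and a mean of -0.12, and neither passed, nor did the other chromatin lists. In all, 8455 genes were higher and 6718 lower, 6326 and 4385 by 2-fold or more, and library size alone moved the median of all genes by 0.298. With p-values adjusted over the list alone, 14 in place of 13 histone acetylation genes were higher and no other count differed.

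B220+ cells against CLP followed B lineage maturation, with B lineage genes higher and cell cycle genes and 6 of the 9 chromatin lists lower in B220+ cells. Ms4a1, the CD20 gene, was 6360-fold higher in B220+ cells (1110 ± 9.1 against 0.168 ± 0.11 CPM, n = 3 each, log2 fold change 12.6, SE 0.078, adjusted p = 8.8e-87), Vpreb3 658-fold and the MHC class II gene H2-Ab1 135-fold (3250 ± 35 against 24.0 ± 0.44). Mki67 was 13.7-fold lower (132 ± 2.6 against 1810 ± 25, adjusted p = 2.0e-123), Rad21 9.66-fold and Chd4 5.92-fold lower. Fcmr, the IgM Fc receptor, was 2970-fold higher. Grik5 had no count in B220+ cells (at least 453-fold lower against 3 counts over the group), nor did the heat shock gene Hspa1b (at least 430-fold). Log2 fold changes fell with transcript length (Spearman rho -0.402 across genes).

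All 20 B lineage genes (median 6.91, camera adjusted p = 2.83e-13), all 10 MHC class II presentation genes (median 5.65, adjusted p = 3.37e-08) and all 9 plasma cell genes (median 2.43, adjusted p = 0.000179) were higher, each with p-est = 0.0876. Lymphoid priming had 11 of 16 higher and 5 lower (median 1.46, adjusted p = 0.00686, p-est = 0.141), with Ccr9 101-fold higher and Notch1 5.13-fold lower. Genes of other lineages rose too. Plasmacytoid dendritic cell genes were higher in 9 of 10 and lower in 1 (median 3.94, adjusted p = 1.89e-05), with Klk1 4390-fold higher (431 ± 6.3 CPM) and Siglech at 1560 ± 10. T lineage genes were higher in 21 of 22 and lower in 1 (median 3.11, adjusted p = 1.09e-07), with Cd4 254-fold higher (204 ± 5.3 CPM), and all 18 neutrophil maturation genes were higher (median 6.40, adjusted p = 8.69e-09), with Ifitm6 at 122 ± 0.90 CPM and Ly6g at 39.5 ± 1.1 against 0.0297 ± 0.027. The p-est was 0.108 for the dendritic and T lineage lists and 0.113 for the neutrophil list. Stromal and endothelial genes were lower by 2-fold or more in 8 of 12 (median -4.94), as were 11 of 12 mast cell, basophil and eosinophil (median -4.76) and 13 of 15 megakaryocyte genes (median -4.41), none of them tested here.

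All 10 cohesin and CTCF genes were lower (median -1.63, adjusted p = 2.23e-06), as were 29 of 36 chromatin remodelling genes with 5 higher (median -1.28, adjusted p = 6.36e-07) and 11 of 12 heterochromatin genes with 1 higher (median -1.45, adjusted p = 0.000179), each with p-est = 0.108. MLL/COMPASS (14 of 16 lower, 1 higher, median -1.25, adjusted p = 3.96e-05) and DNA methylation (11 of 14 lower, 2 higher, median -1.18, adjusted p = 0.00231) each had p-est = 0.141, with Kmt2b 18.9-fold, Mbd2 9.42-fold and Dnmt1, the maintenance methyltransferase, 2.46-fold lower. Polycomb repressive complex 1 had 14 of 20 lower, 4 higher and 2 not passing (median -1.13, adjusted p = 0.00686, p-est = 0.175), with Bmi1 5.09-fold lower and Cbx7 4.35-fold higher. Without the GC and length trend, DNA methylation (0.136) and Polycomb repressive complex 1 (0.0809) no longer passed. Polycomb repressive complex 2 (0.191), histone acetylation (0.562) and demethylases (0.0593) did not pass.

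Oxidative phosphorylation genes were all higher, 21 of 21 (median 0.92, adjusted p = 8.69e-09, p-est = 0.108), Cox4i1 by 2.97-fold. Replication (17 of 20 lower, 3 not passing, median -0.46, adjusted p = 0.000192, p-est = 0.175) and mitosis (15 lower, 3 higher, 2 not passing, median -0.47, adjusted p = 0.00245, p-est = 0.269) were lower, as were immediate-early genes (12 of 16 lower, 3 higher, 1 not passing, median -1.80, adjusted p = 0.000954, p-est = 0.175), Fosb by 44.8-fold. Ribosome biogenesis had 14 of 18 lower and 4 higher (median -0.36, adjusted p = 0.0243, p-est = 0.383), and was lost with the trend taken out (0.439), where Nop58, 1.84-fold lower, turned to 0.294. In all, 8076 genes were higher and 8705 lower, 4953 and 6268 by 2-fold or more. The median of all genes moved by -0.129 with library size alone and by -0.153 without the GC and length trend. Adjusted over the list alone, 5 in place of 4 Polycomb repressive complex 1 genes were higher, the other counts being unchanged.

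CD3e T cells were also set against CLP, the T lineage counterpart. Cd3d, a chain of the T cell receptor complex, was 1290-fold higher (485 ± 3.5 against 0.371 ± 0.11 CPM, n = 3 each, log2 fold change 10.3, SE 0.069, adjusted p = 4.2e-127), Cd3g 758-fold and the kinase gene Lck 57.9-fold. Mki67 was 23.9-fold lower (76.1 ± 3.0 against 1810 ± 25, adjusted p = 6.4e-129), and the Polycomb gene Suz12 18.6-fold lower. Cd40lg, the CD40 ligand of helper T cells, had no count in CLP (at least 619-fold higher against 3 counts over the group). Ephb2 had no count in CD3e T cells (at least 438-fold lower), and Epx was 290-fold lower.

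All 22 T lineage genes (median 6.87, camera adjusted p = 4.24e-15) and all 12 NK cell genes (median 3.81, adjusted p = 3.33e-07) were higher, and so were 19 of 20 B lineage genes with 1 lower (median 4.15, adjusted p = 6.83e-08), each with p-est = 0.0879. Ccl5 was 150-fold and Tbx21, the T-bet gene, 52.0-fold higher, Ms4a1 was at 134 ± 5.3 CPM, and Cd24a was 2.16-fold lower. All 18 neutrophil maturation genes were higher (median 7.05, adjusted p = 1.45e-09, p-est = 0.0961), with Il1b at 64.3 ± 1.5 and Ly6g at 33.5 ± 1.6 CPM, and C1qb, whose reads can be shared with other C1q genes, was at 570 ± 6.8 against 0.120 ± 0.022. Erythroid genes were lower in 15 of 22, higher in 6, with 1 not passing (median -1.38, adjusted p = 0.0152, p-est = 0.272), Zfpm1, the GATA1 cofactor, by 27.5-fold. Lymphoid priming did not pass (8 of 16 higher, 7 lower, adjusted p = 0.325).

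All 20 replication genes (median -1.09, adjusted p = 2.1e-08), all 20 mitosis genes (median -1.67, adjusted p = 9.9e-11) and all 10 cohesin and CTCF genes (median -1.84, adjusted p = 6.73e-07) were lower, as were 30 of 36 chromatin remodelling genes with 4 higher (median -1.98, adjusted p = 9.28e-09), 11 of 12 heterochromatin genes with 1 higher (median -1.85, adjusted p = 5.37e-05) and 12 of 14 DNA methylation genes with 1 higher (median -1.29, adjusted p = 4.46e-05), each with p-est = 0.0879. MLL/COMPASS had 14 of 16 lower and 1 higher (median -1.44, adjusted p = 4.41e-06, p-est = 0.104), with Kmt2d 8.24-fold lower. Polycomb repressive complex 2 (9 of 12 lower, 2 higher, median -0.61, adjusted p = 0.0163, p-est = 0.209), Polycomb repressive complex 1 (13 of 20 lower, 5 higher, median -1.28, adjusted p = 0.0197, p-est = 0.272) and histone acetylation (19 of 29 lower, 7 higher, median -0.39, adjusted p = 0.0202, p-est = 0.303) passed, and did not pass without the GC and length trend (0.0831, 0.0976 and 0.294). Ezh2 was 7.2-fold lower and Ezh1 2.31-fold higher, Cbx7 was 5.58-fold higher, and the acetyltransferase gene Ep300 was 3.55-fold lower. Oxidative phosphorylation had 19 of 21 higher, 1 lower and 1 not passing (median 0.68, adjusted p = 1.72e-06, p-est = 0.125), and its median was -0.0296 with the trend taken out (adjusted p = 0.368). Ribosome biogenesis (0.0753), demethylases (0.0753) and immediate-early genes (11 of 16 higher, 5 lower, median 0.65, mean -0.01, adjusted p = 0.0605) did not pass. In all, 8287 genes were higher and 8531 lower, 5287 and 6105 by 2-fold or more. The median of all genes moved by -0.152 with library size alone and by -0.143 with the trend taken out, and no count differed adjusted over the list alone.

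**Figure D4:**
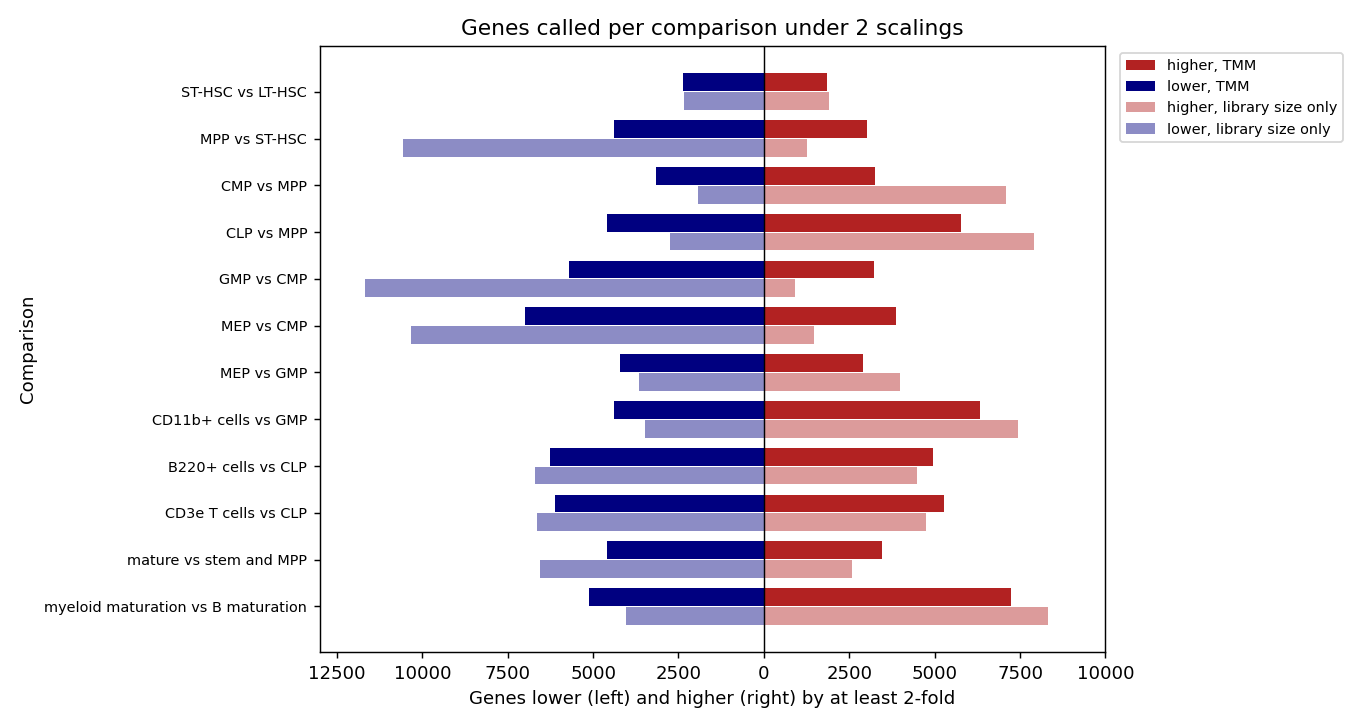
Number of genes higher (to the right) and lower (to the left) by 2-fold or more at adjusted p below 0.05 in each of the 12 comparisons, by TMM scaling and by library size alone. With library size alone, MPP against ST-HSC has 1260 higher and 10578 lower genes in place of 3013 and 4383.

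The 3 mature fractions together were compared with LT-HSC, ST-HSC and MPP, the ends of the hierarchy. Stem cell genes such as Angpt1 were lower in mature cells (6.98 against 326 CPM, log2 fold change -5.51, SE 0.028, 3 against 3 populations, edgeR adjusted p = 1e-140). SE and p omit spread between populations. The de novo methyltransferase gene Dnmt3b was 6.57-fold lower (11 against 71.2 CPM, adjusted p = 2.6e-102) and Tet1 3.65-fold lower. Satb1, a genome organizer, was 3.61-fold, Cbx7 2.17-fold and Ezh1 1.85-fold higher. The largest rises were Cd209a (563-fold), Fcmr (542-fold) and S1pr5 (13.7 against 0.0104 CPM), and the largest falls Samd12 (198-fold), Pkia (180-fold) and Nkx2-3 (152-fold).

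Of the other chromatin genes fixed for this comparison, Dnmt3a was 1.77-fold, Bmi1 1.78-fold, Cbx2 2.31-fold, Smarca2 1.45-fold, Kmt2a 1.27-fold, Dnmt1 1.23-fold and Uhrf1 1.04-fold lower. Tet3 (1.24-fold), Hdac7 (1.21-fold), Tet2 (1.14-fold) and Ezh2 (1.11-fold) were higher by TMM scaling and turned to -0.115, -0.147, -0.231 and -0.265 with library size alone. The heterochromatin list had 9 of 12 genes lower, 2 higher and 1 not passing (median -0.28, camera adjusted p = 0.0366, p-est = 0.291), with Cbx5 2.06-fold lower and Daxx 2.0-fold higher, a call lost without the GC and length trend (0.0872). DNA methylation, both Polycomb lists, MLL/COMPASS, histone acetylation, demethylases (adjusted p = 0.0743), remodelling (median 0.03, mean -0.07) and cohesin (-0.13 and 0.01) did not pass. Stem cell identity had 25 of 26 lower and 1 higher (median -3.92, adjusted p = 1.53e-10), ribosome biogenesis 17 of 18 lower and 1 not passing (median -0.90, adjusted p = 9.85e-08) and immediate-early genes 13 of 16 lower, 2 higher and 1 not passing (median -0.93, adjusted p = 5.21e-05), each with p-est = 0.291. Replication had 16 of 20 lower, 3 higher and 1 not passing (median -0.45, adjusted p = 0.000215, p-est = 0.293). Mitosis had 19 of 20 higher and 1 lower (median 0.30, adjusted p = 4.27e-05, p-est = 0.291), Ube2c by 1.65-fold, and the median turned to -0.122 with library size alone. Oxidative phosphorylation did not pass (9 of 21 higher, 9 lower, median 0.01 with a test pointing down, adjusted p = 0.852). Neutrophil (median 7.01), B lineage (5.87) and T lineage genes (5.54), not tested here, were higher. In all, 7776 genes were higher and 8824 lower, 3458 and 4602 by 2-fold or more. Library size alone moved the median of all genes by -0.419 and the split to 5102 higher and 12199 lower. Adjusted over the list alone, 9 in place of 8 MLL/COMPASS genes were higher, the other counts being unchanged.

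Myeloid maturation (CD11b+ cells minus GMP) was set against B lineage maturation (B220+ cells minus CLP) by testing the difference of the log2 fold changes. Alox15, a lipoxygenase, had the largest positive difference (log2 11.2, SE 0.096, 12 libraries, edgeR adjusted p = 3.8e-116), before Tarm1 (11) and Syne1 (10.7). The largest negative differences were those of Hist1h2ao (-10.8, SE 0.46) and Hist1h2ap (-9.54, SE 1.4), which can share reads with near copies and are uncertain, and of Smtnl2 (-8.90). Atp5b, which fell in myeloid maturation, differed by -4 (SE 0.035, adjusted p = 2.0e-115), and Mki67, which fell in B lineage maturation, by 5.65 (SE 0.046, adjusted p = 1.2e-117).

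Oxidative phosphorylation genes had a negative difference in 21 of 21 (median -2.76, camera adjusted p = 9.8e-16, p-est = 0.0969), ribosome biogenesis in 16 of 18 with 2 positive (median -2.23, adjusted p = 3.53e-08, p-est = 0.118) and replication in 14 of 20 with 5 positive (median -0.80, adjusted p = 0.000601, p-est = 0.278). All 10 cohesin and CTCF genes (median 1.85, adjusted p = 4.31e-06, p-est = 0.0969), 28 of 36 chromatin remodelling genes with 6 negative (median 2.01, adjusted p = 0.000117, p-est = 0.148), 13 of 16 demethylases with 3 negative (median 1.56, adjusted p = 0.000937, p-est = 0.118) and 12 of 16 MLL/COMPASS genes with 3 negative (median 2.06, adjusted p = 0.00641, p-est = 0.286) had a positive difference. Immediate-early genes (12 of 16 positive, 3 negative, median 0.92, adjusted p = 0.0229, p-est = 0.374) and mitosis (12 of 20 positive, 7 negative, median 0.67, adjusted p = 0.0419, p-est = 0.445) passed as well, mitosis not with the replicate number as a block (0.0562). The demethylase (0.694) and remodelling (0.245) calls were lost without the GC and length trend, and the differences rose with transcript length (Spearman rho 0.434 across genes). DNA methylation (0.168), Polycomb repressive complex 2 (0.302), Polycomb repressive complex 1 (0.231), heterochromatin (0.0569) and histone acetylation (0.742) did not pass. In all, 8616 genes had a positive and 6648 a negative difference, 7243 and 5108 by 2-fold or more. The median of all genes moved by 0.404 with library size alone and by 0.198 with the trend taken out, and no count differed adjusted over the list alone. Over the 12 comparisons, 134 list calls passed with the preset correlation and 8 held with an estimated one, the stem cell, lymphoid priming and megakaryocyte lists in ST-HSC against LT-HSC and the stem cell, granulocyte-monocyte, replication, mitosis and oxidative phosphorylation lists in MPP against ST-HSC.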

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

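Of the tests in this part, those of scaling, of cycling cells and of the GC and length trend were chosen only after the results were seen. The response of 9 gene lists differed between myeloid maturation (CD11b+ cells minus GMP) and B lineage maturation (B220+ cells minus CLP) by a test of the difference itself. The median difference was -2.76 for oxidative phosphorylation (side medians -1.81 and 0.915), -2.23 for ribosome biogenesis (-2.44 and -0.36), -0.802 for replication (-1.24 and -0.459), 0.673 for mitosis (0.147 and -0.47), 0.917 for immediate-early and stress genes (-0.91 and -1.8), 2.06 for MLL/COMPASS (0.346 and -1.25), 1.56 for histone demethylases (0.724 and -0.482), 2.01 for chromatin remodelling (0.392 and -1.28) and 1.85 for cohesin and CTCF (0.606 and -1.63). None passed with an estimated correlation between genes, the lowest adjusted p being 0.0969. Lists of other cell types, not tested here, moved further, with medians of 6.97 for stromal and endothelial, 4.65 for mast cell, basophil and eosinophil, 4.39 for megakaryocyte and 4.16 for erythroid genes.

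Which libraries carry the chromatin part was not tested. In CLP against MPP, outside this contrast, 122 of 165 chromatin-regulator genes were higher in CLP and 33 lower. Taking out the GC and length trend moved their median from 1.26 to 0.514 and that of all genes from 0 to 0.172. Their ratio of 0.409 was under a bound of 0.5 set beforehand. A technical length effect could account for much of the rise, though the correction can also take out real differences that follow length. Scaling moves all genes alike, but the chromatin genes stood 1.26 above the median of all genes, so it was not the cause. Replication genes did not move with them (ratio -0.184), which speaks against more cycling cells among CLP as the whole cause. More cells in mitosis stay open. The mitosis list did not pass (10 of 20 higher, 9 lower, adjusted p = 0.344). It did with the trend taken out (0.0465) and library size alone (0.000968), and Mki67 stood at 1810 CPM.

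In each of the 10 comparisons of 3 with 3 libraries, only the real split of 10 called as many genes, and 10 cannot give a share under 0.05. These counts come from fits of only the libraries compared. The real split called at least 10550 genes and no other more than 1. For mature cells against stem cells and MPP, fitted as 2 groups, 1 of 100 splits called as many genes (8411, highest other 5510), and for the difference of maturation steps 1 of 100 (14232, highest other 3639). Splits of libraries cannot test the grouping of populations.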

How the results depend on the processing

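Of the alternatives in this part, the 2-fold test, the GC and length trend, the fit without CLP and the separate dispersion estimate were chosen after the results were seen. With relative log expression factors, DESeq2, limma-voom, the GC and length trend taken out, only the populations compared in the fit and dispersion estimated before the fit, all 48 counts of genes stayed within 1.5 times, as did all 360 with 1 library left out and all 32 without CLP. All 659 named values kept their direction and side of the threshold under DESeq2, relative log expression factors, no filter and comparison-only fits. Of 134 list calls, 3 were lost with relative log expression factors, 2 of 77 without CLP, 5 with 1 library left out (925 kept), 15 with comparison-only fits (adjusted p up to 0.267) and 23 with the trend taken out, besides 2 in which the test also turned direction. With library size alone 5 were lost and the test turned in 6 more. Lists that had not passed did so in 18 cases with the trend taken out, 34 with library size alone, 23 without a filter and 1 with relative log expression factors. Genes with few counts limit the largest folds, and p-values rest on replicates that may be technical.

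The labels give the replicate numbers no shared animal or batch, and 20 of 165 same-number pairs had a correlation of deviations over 0.1, so the libraries were not taken as paired. Still, the mean was 0.032 for the same number and -0.016 for different ones, and 26 of 33 libraries correlated best with their own number, a hint from the data of something shared. With the number as a block, 6161 genes were higher and 6988 lower in ST-HSC against LT-HSC in place of 6103 and 6975, and of all calls only mitosis in the difference of maturation steps was lost (0.672, adjusted p = 0.0562).

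In ST-HSC against LT-HSC, 3720 and 4591 genes were higher and lower by 2-fold or more without a filter (1838 and 2377 with it), and in CMP against MPP 5469 were higher (3261), more genes being tested. Tested against a 2-fold change, 1028 and 1537 passed in ST-HSC against LT-HSC, 2822 lower (4383) in MPP against ST-HSC and 1897 higher (3261) in CMP against MPP, as a stricter test gives. With library size alone, 17 of the 48 counts moved by over 1.5 times: in MPP against ST-HSC 2271 higher and 15159 lower, 1260 and 10578 by 2-fold or more (6879, 8178, 3013 and 4383 with TMM); in CMP against MPP 13061, 3099, 7102 and 1920 (7156, 7166, 3261 and 3161); in GMP against CMP 1991, 15079, 918 and 11684 (6510, 8565, 3234 and 5715). In CLP against MPP 4970 were lower, 2735 by 2-fold or more (7650 and 4586), in MEP against CMP 3405 were higher, 1459 by 2-fold or more (6973 and 3875), and in mature against stem cells 5102 were higher (7776). The cause was not tested.

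With an estimated correlation 3 lists passed in ST-HSC against LT-HSC (5 with the preset one), 5 in MPP against ST-HSC (10) and 0 in each of the other 10 comparisons. With the trend taken out, 12 lists passed in ST-HSC against LT-HSC in place of 5.

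Signs turned with library size alone for Ptprc in B220+ cells against BM (0.461), Ikzf1 (-0.286), Ncl (-0.0491), Dkc1 (-0.22), lymphoid priming (-0.0712), replication (-0.0688) and ribosome biogenesis (-0.329) in MPP against ST-HSC, for Mcm5 (0.0106), erythroid genes (0.218), replication (0.36) and mitosis (0.401) in CMP against MPP, for replication (0.357) in CLP against MPP, for Ccnb1 (-0.0449), Npm1 (-0.301), Nop2 (-0.218), Mta2 (-0.239), monocyte and macrophage genes (-0.373), replication (-0.325), mitosis (-0.771) and ribosome biogenesis (-0.593) in GMP against CMP, and for Tet2 (-0.231), Tet3 (-0.115), Ezh2 (-0.265), Hdac7 (-0.147) and mitosis (-0.122) in mature against stem cells. With the GC and length trend taken out they turned for Tcf4 (-0.0715) and DNA methylation (-0.0684) in CLP against MPP, chromatin remodelling (0.00724) in GMP against CMP, Nop58 (0.294) in B220+ cells against CLP and oxidative phosphorylation (-0.0296) in CD3e T cells against CLP. The cause was not tested.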

Other observations

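In this part, the tests of the label swap, the GC and length trend, the lymphoid-primed cells, the mature cells and both of transfer were chosen only after the results were seen. Dntt was lower in CLP than in CMP (log2 fold change -3.47, SE 0.046, n = 3 each, edgeR adjusted p = 8.5e-28), Rag2 (-2.44, SE 0.076, adjusted p = 1.7e-57) and Flt3 (-1.56, SE 0.025, adjusted p = 2.6e-86) were lower too, and Rag1 was higher (1.32, SE 0.082, adjusted p = 8.9e-31). These are genes of early lymphoid progenitors, and of 16 lymphoid priming genes 6 were lower and 4 higher in CLP by 2-fold or more (median 0.103). For the 3 lower genes GC content and length were not the cause, since with the trend taken out the smallest difference was still 1.81, while that of Rag1 fell to 0.569. Of the 16 genes, 11 (0.688) were at least 2-fold higher in CMP than in GMP and MEP, which lymphoid-primed cells among CMP would give. A swap of the CMP and CLP labels met 3 of 6 conditions and stays open: the granulocyte-monocyte, erythroid and megakaryocyte medians were higher in CLP (1.09, 0.421 and 1.33) but so were the B lineage median (0.315, or 1.05 with the trend taken out), Rag1 and, slightly, Il7r (0.0944, adjusted p = 0.03; 0.279 with the trend taken out), and of the gate genes Kit, higher in CMP (155 against 57.9 CPM), speaks against a swap and Ly6a, also higher in CMP (15.2 against 2.20), for it.

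MPP held transcripts of mature cells. Of 39 plasma cell, macrophage and basophil genes, 34 (0.872) were higher in MPP than in both ST-HSC and CMP, led by Jchain (7380 CPM), Prg2 (3610), Prss34 (3500) and Vcam1 (2190), which mature cells in the sort could give. The lineage depletion before sorting would remove such cells where they carry its antigens, and which antigens it holds is not given in the sources used here. Of the list genes, 7 of 9 plasma cell genes were at least 2-fold higher in MPP than in ST-HSC, as were all 12 mast cell, basophil and eosinophil genes, while GMP also held 2580 CPM of Prg2. Transfer of reads or RNA from other libraries, tested by order of abundance, stayed open: Jchain and Ighm were at least 16.1 times the mean of the other sorted populations, yet S100a9 was also higher in MPP than in ST-HSC (0.393, adjusted p = 0.04). A further test had a bound of 5 genes set after the levels were known. With TMM scaling 8 genes, among them Jchain, C1qb (951 CPM) and Axl (466), were higher in each MPP library than in any other library. This speaks against transfer for them, but read shares were not compared, and other genes stay open.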
